A study of Mus musculus with 2 samples.

How the data were processed

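Cells were taken from mouse lungs at postnatal day 10 and sorted by FACS into epithelial, immune, endothelial and mesenchymal cells, per the labels' protocols. They were loaded on the 10x Chromium platform with the 3' kit (version 2 chemistry) and sequenced on a NextSeq500, per the same protocols. The deposited values are raw UMI counts per gene and barcode for 27998 genes, made by the authors from these libraries. Cell Ranger, Seurat and mm10 are named in the submitters' processing notes. Their versions, the annotation release and the filters are not given in the sources used here. The lowest barcode held 2278 UMIs in the control and 3874 UMIs in the mutant library, so shallower barcodes had been left out before deposit. No cell annotation by the authors was used here. Groups came from the genotype labels, with 1 control and 1 mutant library.

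Median depths were 5943 UMIs and 1981 genes per barcode in the control and 8305 UMIs and 2677 genes in the mutant. Barcodes were kept with at least 500 genes and under 10% mitochondrial counts. In each library 1 barcode had fewer genes, and 320 control and 132 mutant barcodes had more mitochondrial counts, leaving 4141 and 4418 cells. Doublets were scored per library from 2 simulated doublets per cell, by the share of simulated profiles among the nearest neighbours. The expected rate was 0.8% per 1000 cells and the threshold came from the scores' histogram. This marked 132 control cells (3.19%) and 167 mutant cells (3.78%), which were removed, while 57.9% and 59.1% of the simulated doublets scored above the threshold, so some doublets will have stayed in.

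Counts per cell were scaled to 10000 and log transformed. The 2000 most variable genes, without cell cycle, mitochondrial, ribosomal and sex-linked genes, entered 30 principal components, 20 nearest neighbours, a shared-neighbour graph and Leiden clustering at resolution 1 with seed 1, both libraries together and without integration. Clusters were first assigned to a lineage and then clustered again within it, which gave 13 epithelial, 9 endothelial, 14 mesenchymal and 8 immune clusters. A cluster took a name, read as that type's likeness, when its mean log2 fold over marker genes was at least 1.5 and at least 3 markers were seen in at least 10% of its cells. It also needed no more markers of a rival type than of its own among its top 10 genes. Clusters with at least 3 markers of another lineage at their median were called mixed, and their 48 control and 58 mutant cells were left out. The AT1 compartment was defined as epithelial cells in no AT2-like, club-like, ciliated-like, neuroendocrine-like or basal-like cluster, because AT1 markers may themselves differ in the mutant. It held 562 control and 2236 mutant cells with median depths of 6473 and 12278 UMIs.

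For each of 5 classes, counts were summed over the cells of a library and divided by the class total to give counts per 1000000 (CPM), and the ratio was mutant over control. Intervals were exact at 95%, conditional binomial for ratios. A gene at 0 in 1 library took 3 counts over the class as its floor, which gives a bound. List medians covered listed genes with at least 20 UMIs over both libraries, for lists of at least 5 such genes. Each median was placed as a percentile among 10000 random lists of the same size, matched within 50 ranks of mean expression to each side, as a description of these libraries. The interval of a list median is the exact binomial interval of a median and treats genes as independent. Other scalings moved the median of all genes by over 0.1 (log2) in the AT1 compartment, AT2-like cells and immune cells, where medians are given less the median of all genes. Shares of cells with a UMI were computed after thinning each cell to 1500 UMIs, which left out no cell.

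The markers, the 28 gene lists, the definition of the compartment, the rule for named genes and 18 alternatives were fixed before the data were examined. The thresholds for naming clusters, the interval of list medians, the choice of which lists to describe in each class and 2 further alternatives were chosen after seeing the data. Named genes were, per list, those with the highest summed count in the library where they were higher and those with the largest ratios. Per class they were also the 10 largest and 10 smallest ratios among genes with at least 50 UMIs and at least 100 CPM in the higher library. Genes whose log2 ratio had the same sign and at least 0.5 of the size in each other lineage were set apart as differing library-wide. The result of 1 gene that the rule names is not reported here. Of the listed genes, 5 are absent from the matrix under the symbol used (Cblif, Cebpd, Ccn1, Ccn2 and Vegfd). Both libraries held Xist (35157 and 69852 UMIs) and 1 UMI each over 4 Y-linked genes.

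The code was tested on simulated counts with known folds. Class totals were drawn as independent Poisson counts, which the intervals assume. The coverage therefore checks the code, and not the spread between cells or animals or the assignment of cells to classes. In the AT1 compartment, 50 genes changed by 2-fold came back at a median log2 of 0.99 and 47 genes lowered to 0.5 at -1.03, with 96.0% and 91.5% of intervals covering the truth. Of 12505 unchanged genes there, 96.1% of intervals covered 0. In endothelial cells, 2-fold genes came back at 1.05 and genes lowered to 0.5 at -1.02, with 98% and 100% coverage. Simulated unchanged lists lay inside the central 95% of random lists in 93 of 100 draws for the compartment and in 97 of 100 for endothelial cells.

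The alternatives were all barcodes as given, stricter cell filters, doublets kept, other resolutions, clustering without listed genes, each library clustered alone, scaling by the median ratio or a trimmed mean, a mean over cells and subtraction of free RNA. Others were lower and higher count limits for listed genes, other thinning depths, and the compartment taken as all epithelial cells, as single cells classed by their AT2, club and ciliated marker UMIs, or as non-cycling cells. Non-cycling cells had at most 3 UMIs of S, G2 and M phase genes in sum, not scaled to depth. Free RNA was taken, per gene and library, as the lowest CPM among the other lineages. For genes expressed in every lineage this also removes the cells' own RNA and can leave a library at the floor. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9 were used. The Nkx2-1 coordinates are those of the GENCODE M21 annotation of mm10 (GRCm38).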

Results

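Single-cell RNA profiles were collected from mouse lungs at postnatal day 10, when the alveolar surface is still being built. Epithelial, immune, endothelial and mesenchymal cells had been sorted by FACS, per the labels' protocols, and 1 library was made from a control and 1 from a mutant in which the labels name Nkx2-1 together with Aqp5. Nkx2-1 encodes a homeobox transcription factor of the lung epithelium. Aqp5 encodes a water channel of alveolar type 1 (AT1) cells, the flat cells of gas exchange, and its locus is known to have been used to drive recombination in them. The series asks how Nkx2-1 controls the development and maintenance of AT1 cells. The control library held 4461 barcodes and 29862980 unique molecular identifiers (UMIs), with a median of 5943 UMIs per barcode, and the mutant library held 4551 barcodes and 47271104 UMIs, with a median of 8305. After filtering, 4009 control and 4251 mutant cells were used. With 1 library per group there was no replicate check, so values describe these 2 libraries. Intervals are exact 95% intervals, Poisson for counts and Clopper-Pearson for shares, and cover counting error only. Those of list medians are instead binomial intervals of a median over the listed genes and do not cover spread between animals.

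Nkx2-1 was lower in the mutant library in the cells left after setting aside alveolar type 2 (AT2), club and ciliated clusters, here called the AT1 compartment. The gene (ENSMUSG00000001496) lies on the minus strand of chromosome 12 of mm10, from 56531958 to 56536908, and has 2 annotated transcripts. In the compartment it had 485 counts per 1000000 (CPM; 464 to 508, 1859 UMIs) in the control and 13.7 CPM (12.4 to 15.1, 423 UMIs) in the mutant, 35.4-fold lower (31.8 to 39.4). On the log2 scale this was -5.15, against -4.53 as a mean over cells, -3.58 over all epithelial cells, -3.68 in non-cycling cells, -5.96 with single cells classed and -1.38 in AT1-like clusters alone. In AT2-like cells, the surfactant-producing type, it had 348 CPM (336 to 360) in the control and 316 CPM (289 to 344) in the mutant, a ratio of 0.908 (0.826 to 0.996). In airway cells it had 207 CPM in the control and 134 CPM in the mutant, a ratio of 0.647 (0.499 to 0.831). Endothelial, mesenchymal and immune cells of either library had at most 9.87 CPM. After thinning every cell to 1500 UMIs, 49.8% (45.6 to 54.0) of control and 2.24% (1.66 to 2.94) of mutant compartment cells had an Nkx2-1 UMI, against 89.1% and 7.47% before thinning. In AT1-like clusters alone the mutant share was 23.7%, in non-cycling cells 5.09%, over all epithelial cells 5.60% and with single cells classed 1.34%. Values in AT1-like clusters alone, in this paragraph and below, compare mostly control cells of cluster 4 (510) with mutant cells of cluster 8 (174). They thus also compare those clusters. The background in endothelial cells after thinning was 0.846% in the control, with a median depth of 4383 UMIs. It was 0 of 487 cells in the mutant, with a median depth of 5304 UMIs. The libraries count 3' tags and the labels do not say which part of Nkx2-1 was deleted, so the tag count alone does not check the deletion.

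**Figure D1:**
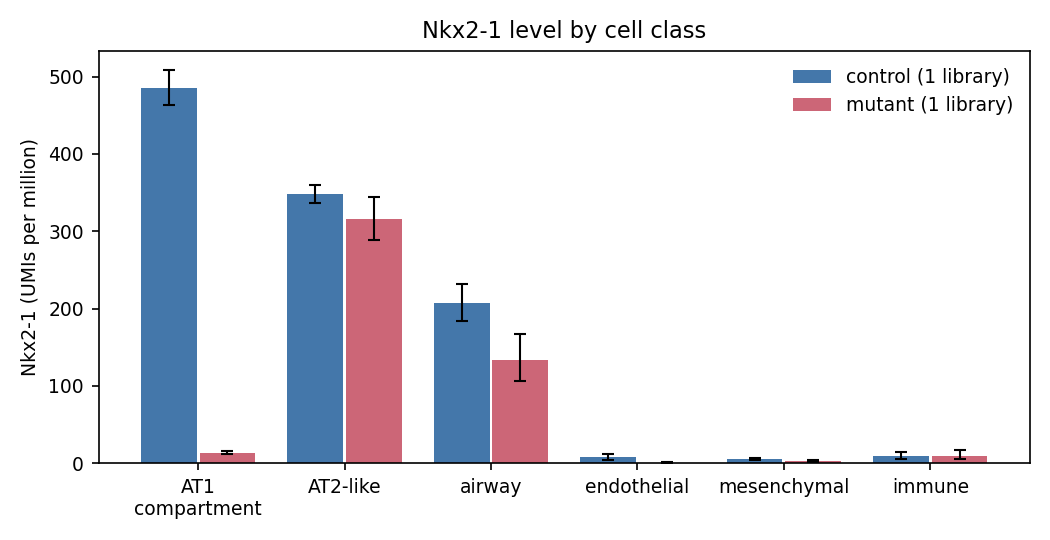
Nkx2-1 in CPM on the vertical axis by cell class, with bars for the control and the mutant library and exact 95% Poisson intervals as error bars. The AT1 compartment had 485 CPM in the control and 13.7 CPM in the mutant, while AT2-like cells had 348 and 316 CPM.

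The epithelium of the mutant library was made up differently. The AT1 compartment took 562 of 1958 control epithelial cells (28.7%, 26.7 to 30.8) and 2236 of 2517 mutant epithelial cells (88.8%, 87.5 to 90.0). Clustering without the listed AT1, AT2, gut and transcription factor genes gave 29.5% and 88.9%. The control share was 52.3% with each library clustered alone, where AT2-like cells took 40.9% of control epithelial cells. It was 15.9% with single cells classed one by one. AT2-like cells took 64.5% (62.3 to 66.6) and 8.42% (7.37 to 9.58), and airway cells 6.79% and 2.74%. Most control compartment cells lay in an AT1-like cluster of 510 control and 3 mutant cells, while most mutant compartment cells lay in clusters with no control cell, so those clusters may reflect the library as well as a cell type. Clusters that matched no fixed set of markers held 0.204% of control and 81.8% of mutant epithelial cells. The FACS sort sets shares between lineages and may also act on shares within the epithelium, so only the latter are given. In the compartment the median of all genes was 0.16 (log2) higher in the mutant, and list medians there are given relative to it.

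AT1 genes were lower in the mutant compartment, from the receptor gene Ager to the cytoskeletal regulator Rtkn2. Of 46 listed AT1 genes, 43 were lower in the mutant and 38 of these by at least 2-fold, with a median log2 ratio of -2.59 (-3.30 to -1.96), at percentile 0 among 10000 matched random lists. Before centring this was -2.43, against -1.67 with each library clustered alone, -1.003 over all epithelial cells and -0.65 in AT1-like clusters alone. The last value does not separate genotype from cluster. Within cluster 8 the summed AT1 list had 43350 CPM in the control and 47094 CPM in the mutant. Ager, the most abundant AT1 membrane marker, had 21893 CPM in the control and 1317 CPM in the mutant (16.6-fold lower). The ligand gene Wnt3a was 42.4-fold lower and Rtkn2 40.7-fold lower. S100a6, a calcium-binding protein gene, was 1.23-fold higher and was also higher in the other lineages. Other AT1 genes, named after their values were seen, were the homeodomain gene Hopx (579 and 44.8 CPM), Aqp5 itself (3080 and 243 CPM) and the angiogenic factor gene Vegfa (783 and 98.9 CPM). Since the labels name Aqp5 in the mutant, the Aqp5 level may also reflect that genotype, which was not tested. Thinned to 1500 UMIs, 99.5% of control and 30.4% of mutant compartment cells had an Ager UMI, against 15.7% and 1.85% of endothelial cells. For listed and named genes with at least 20 UMIs in each library, counting error moved a compartment ratio by at most 1.88-fold either way.

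More genes that AT1 cells use toward their surroundings were lower than higher. Of 29 measured genes for secreted signals, 17 were lower, all by at least 2-fold, and 12 higher, 10 of them by at least 2-fold, with a median of -1.88 (-2.92 to 1.47, percentile 0). Before centring this was -1.72, against -1.01 with doublets kept, -0.93 with each library clustered alone, -0.67 in AT1-like clusters alone and -0.065 over all epithelial cells. The growth factor binding protein gene Igfbp2 was 15.2-fold lower, while the guidance gene Sema3c had 3.92 CPM in the control and 226 CPM in the mutant, 57.7-fold higher. Edn1, which encodes the vasoconstrictor endothelin, had 3 control UMIs and a ratio of 48.3 (16.5 to 234). Of 23 basement membrane genes 17 were lower, with a median of -1.33 (-1.87 to -0.49, percentile 0), although before centring this median was 0.25 over all epithelial cells, -0.48 with each library clustered alone and -0.57 in AT1-like clusters alone. Sparc, a matricellular protein gene, was 10.4-fold lower and the collagen IV gene Col4a3 15.5-fold lower, while the integrin gene Itgb4 had 3 control UMIs and a ratio of 40.5 (13.8 to 197). Of 19 YAP and TAZ target genes, which respond to cell stretch and shape, 12 were lower, with a median of -0.79 (-1.64 to 0.56, percentile 0.375) that was 0.48 before centring over all epithelial cells. Cyr61 was 6.07-fold and Ankrd1 22.1-fold lower, and Myof, a membrane repair gene, was 3.06-fold higher.

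Most measured gastric and intestinal genes were higher in the mutant compartment. Of 17 measured gastric genes, 16 were higher, with a median of 3.21 (1.15 to 6.98, percentile 100), and 13 had no UMI in 1 of the libraries, so that their ratios stand at the bound that 3 counts give. Before centring the median was 3.37, against 1.31 over genes with at least 1 UMI, 6.72 over those with at least 100 and 4.04 with each library clustered alone. The mucus-associated trefoil genes led: Tff2 had 0 CPM in the control and 485 CPM in the mutant (at least 619-fold higher), and Tff1 had 0 and 321 CPM (at least 410-fold higher). The AT1-like clusters alone held 0 Tff2 UMIs in the control and 1 in the mutant, so no ratio is given there. Tff2 UMIs appeared in 24.8% (23.0 to 26.7) of mutant and 0 of 562 control compartment cells after thinning, against 0.821% and 0 of endothelial cells. Of 21 intestinal genes 19 were higher, with a median of 2.09 (0.64 to 3.65, percentile 100). Before centring it was 2.25, against 0.73 over genes with at least 1 UMI, 3.37 over those with at least 100, 3.25 over all epithelial cells, 1.60 with single cells classed and -0.23 in AT1-like clusters alone. Summed, however, the intestinal list had 1274 CPM (1239 to 1311) in the control and 1172 CPM (1160 to 1184) in the mutant. Lgals4, a gut epithelial galectin gene, had 1.31 CPM in the control and 217 CPM in the mutant, Apoa1, an apolipoprotein gene of gut and liver, was at least 67.2-fold higher, and Tspan8 was 2.31-fold lower, with the opposite sign (0.32) over all epithelial cells. All 10 measured gut and liver transcription factor genes were higher, with a median of 2.04 (0.57 to 5.002, percentile 99.98), which before centring was 2.20, but 3.22 over all epithelial cells, 2.83 with each library clustered alone and 2.85 over genes with at least 100 UMIs. Among them the gut and liver regulator Hnf4a was at least 35.8-fold higher, Foxa3, with 2 control UMIs, had a ratio of 50.4 (13.9 to 417) and Klf5 was 2.45-fold higher.

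**Figure D2:**
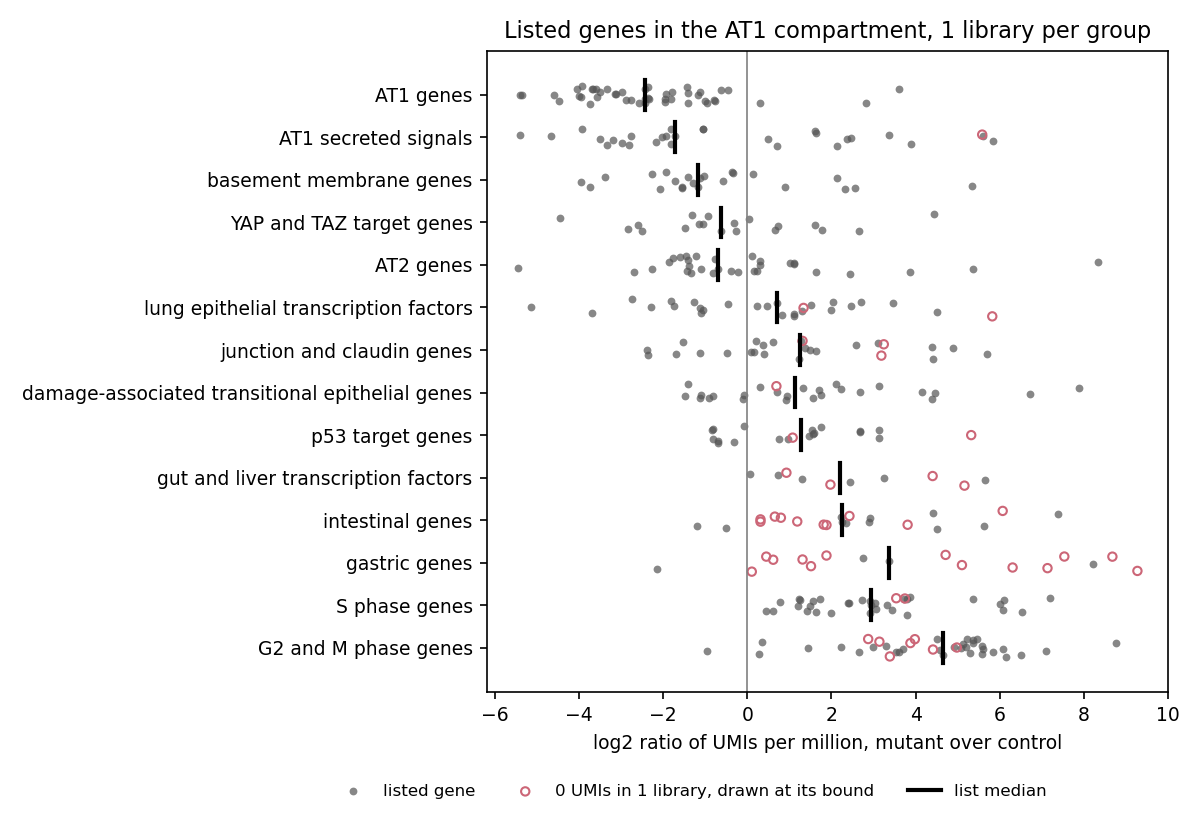
Log2 ratio of CPM, mutant over control, in the AT1 compartment before centring, where each point is 1 listed gene, open circles have 0 UMIs in 1 library and are drawn at their bound, and bars mark list medians. AT1 genes lie mostly below 0 (43 of 46 lower) and gastric genes above 0 (16 of 17 higher).

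Proliferation genes were higher in the mutant compartment. All 34 S phase genes were higher, with a median of 2.78 (1.57 to 3.56, percentile 100), and so were 38 of 39 G2 and M phase genes, with a median of 4.48 (3.46 to 5.14, percentile 100). Summed, the lists had 273 and 625 CPM in the control and 1082 and 1781 CPM in the mutant. Before centring the G2 and M phase median was 4.64, against 2.56 with each library clustered alone, 3.19 over all epithelial cells, 3.61 with free RNA subtracted and 1.57 in AT1-like clusters alone. The S phase median was 2.94, against 2.07, 2.13, 4.06 and 0.098. The 194 control and 275 mutant cells with at most 3 UMIs of these genes in sum were called non-cycling, by a limit not scaled to depth. There the G2 and M phase median was by construction lower, at -0.71 before centring, and the S phase median 0.040. Cks2, a subunit of the cell cycle kinases, was 9.85-fold higher, and Birc5, a mitotic survivin gene with 1 control UMI, had a ratio of 436 (78.2 to 17214). The replication gene Usp1 was 7.60-fold higher. Mki67, the proliferation antigen gene, was seen after thinning in 0 of 562 control and 8.54% of mutant compartment cells, against 3.05% and 14.8% of endothelial cells.

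Transcription factor genes of the lung epithelium went both ways, with 16 higher and 11 lower of 27 and a median of 0.56 (-1.30 to 1.37, percentile 99.98), which was -0.18 before centring in AT1-like clusters alone. Summed, they had 2675 CPM in the control and 2065 CPM in the mutant. The helix-loop-helix gene Id2 was 6.51-fold higher and the Ets factor gene Ehf at least 56.6-fold higher. Of 26 genes of the damage-associated transitional epithelial state 18 were higher, with a median of 0.97 (-0.24 to 2.07, percentile 100). Clu, which encodes the secreted chaperone clusterin, had 35.8 CPM in the control and 8469 CPM in the mutant (237-fold higher), and the stress gene Nupr1 was 105-fold higher. Of 20 p53 target genes 13 were higher, with a median of 1.11 (-0.47 to 1.58, percentile 99.98), which before centring was 1.27, but 2.01 with free RNA subtracted and 0.24 in AT1-like clusters alone. The cell cycle inhibitor gene Cdkn1a was 6.38-fold higher and the apoptosis gene Pmaip1 at least 40.0-fold higher. Of 26 junction genes 20 were higher, with a median of 1.10 (-0.01 to 2.43, percentile 100), among them the adhesion genes Epcam (2.59-fold) and Cdh1 (2.43-fold), the latter encoding E-cadherin. Summed, the junction genes had 5265 CPM in the control and 3317 CPM in the mutant. Their median before centring was 1.26, against 0.61 over genes with at least 1 UMI, 0.48 in non-cycling cells and 0.31 in AT1-like clusters alone. Of 25 interferon and antigen presentation genes 23 were lower, with a median of -1.51 (-1.82 to -0.68, percentile 0), including the interferon-induced Ifit3 (93.2-fold lower) and the antigen presentation gene Cd74 (2.65-fold lower, but 0.97 in log2 in AT1-like clusters alone). This median was -1.35 before centring, against -1.99 with free RNA subtracted, -0.75 with each library clustered alone, -0.71 over all epithelial cells, -0.65 with single cells classed and -0.49 in AT1-like clusters alone. Of 20 immediate early genes 14 were lower, with a median of -0.59 (-0.98 to -0.10, percentile 6.39), including Ier3, 6.59-fold lower. Before centring this was -0.43, against 0.48 with free RNA subtracted and -1.09 over all epithelial cells.

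AT2 genes in the compartment were mixed. Of 31 AT2 genes 18 were lower, with a median of -0.87 (-1.55 to 0.14, percentile 0.02), but before centring this was 1.65 in AT1-like clusters alone and 0.36 after subtracting free RNA. It was -0.71 in the main analysis, -1.65 with doublets kept, -1.32 without listed genes, -2.91 over all epithelial cells and -4.17 with each library clustered alone. Sftpc, the surfactant protein C gene, was 6.48-fold lower, with the opposite sign (1.16) in AT1-like clusters alone. In endothelial cells, which should lack it, it was also 10.4-fold lower, and 94.6% of control and 22.4% of mutant endothelial cells had a Sftpc UMI after thinning. Sftpd, a surfactant collectin gene, was 5.47-fold higher, but had log2 ratios of -0.57 with each library clustered alone and -0.74 over all epithelial cells. Lgi3 was 43.6-fold lower, and Il33, an alarmin gene with 1 control UMI, had a ratio of 324 (58.1 to 12799) that was -0.28 in log2 over all epithelial cells.

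Among genes with at least 50 UMIs and at least 100 CPM in the higher library, the compartment's largest ratio was that of Sprr1a, a cornified envelope gene, which had 0 CPM in the control and 2546 CPM in the mutant (at least 3250-fold higher). Spp1, the osteopontin gene, was at least 696-fold higher, Cym, a gastric protease gene, at least 373-fold and Sprr2a3 at least 336-fold. Scara3, Sorbs2 and Plet1, with 1, 1 and 2 control UMIs, had ratios of 682 (122 to 26933), 589 (106 to 23283) and 318 (88.1 to 2630), and Tff2, Tff1 and Birc5 made up the rest of the 10. The smallest ratios included Aqp1, another water channel gene (1424 and 11.7 CPM, 121-fold lower), Lims2 (83.8-fold), Fjx1 (64.0-fold), the neurotrophin gene Bdnf (47.6-fold), Mrc2 (46.4-fold), Rgcc (45.0-fold), Lgi3, Rtkn2 and Tmod1 (38.1-fold). Genes that were higher or lower in all lineages alike were set apart, and 125 such genes differed by over 2-fold in the compartment.

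The clusters of the compartment differed in these gene groups. Most control cells (510) lay in cluster 4, with 486 CPM of Nkx2-1, 74350 CPM summed over the AT1 list and 46.2 CPM over the gastric list. Cluster 4 also held 3 mutant cells, and the other AT1-like cluster, 8, held 48 control and 174 mutant cells. In cluster 8 Nkx2-1 had 506 CPM (438 to 582) in the control and 183 CPM (163 to 206) in the mutant, and the AT1 list 43350 and 47094 CPM. Clusters 1, 2, 5, 7 and 9 held no control cell. Cluster 1 (600 cells) had 2.12 CPM of Nkx2-1 and 3169 CPM of gastric genes, and clustering without the listed genes gave 3 clusters, not matched cell by cell, of 529, 206 and 24 cells with 2860, 2996 and 2288 CPM of gastric genes. Cluster 2 (579 cells) had 3.29 CPM of Nkx2-1 and 18990 CPM of the AT1 list. The AT1 list had 17524, 34765, 17287 and 16230 CPM in clusters 1, 5, 7 and 9. Gastric genes had 956, 208, 724 and 920 CPM in clusters 2, 5, 7 and 9, and 84.2 and 297 CPM in the mutant cells of clusters 8 and 11. Cluster 5 (389 cells) had 14.1 CPM of Nkx2-1 and 4505 CPM of Ager, and the clustering without listed genes gave a cluster of 357 cells with 15.7 and 4923 CPM. Clusters 7 (240 cells) and 9 (187 cells) had 7372 and 4038 CPM of G2 and M phase genes against 652 CPM in control cluster 4, while clusters 1, 2 and 5 had 493, 346 and 489 CPM. Mki67 alone had 529 and 239 CPM in clusters 7 and 9 and 3.51 CPM (1.81 to 6.13) in control cluster 4. It had 19.7 CPM (16.9 to 22.7), 5.92 CPM (4.32 to 7.92) and 7.41 CPM (5.10 to 10.4) in clusters 1, 2 and 5. The lower list sums in clusters 1, 2 and 5 thus do not show less proliferation there.

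**Figure D3:**
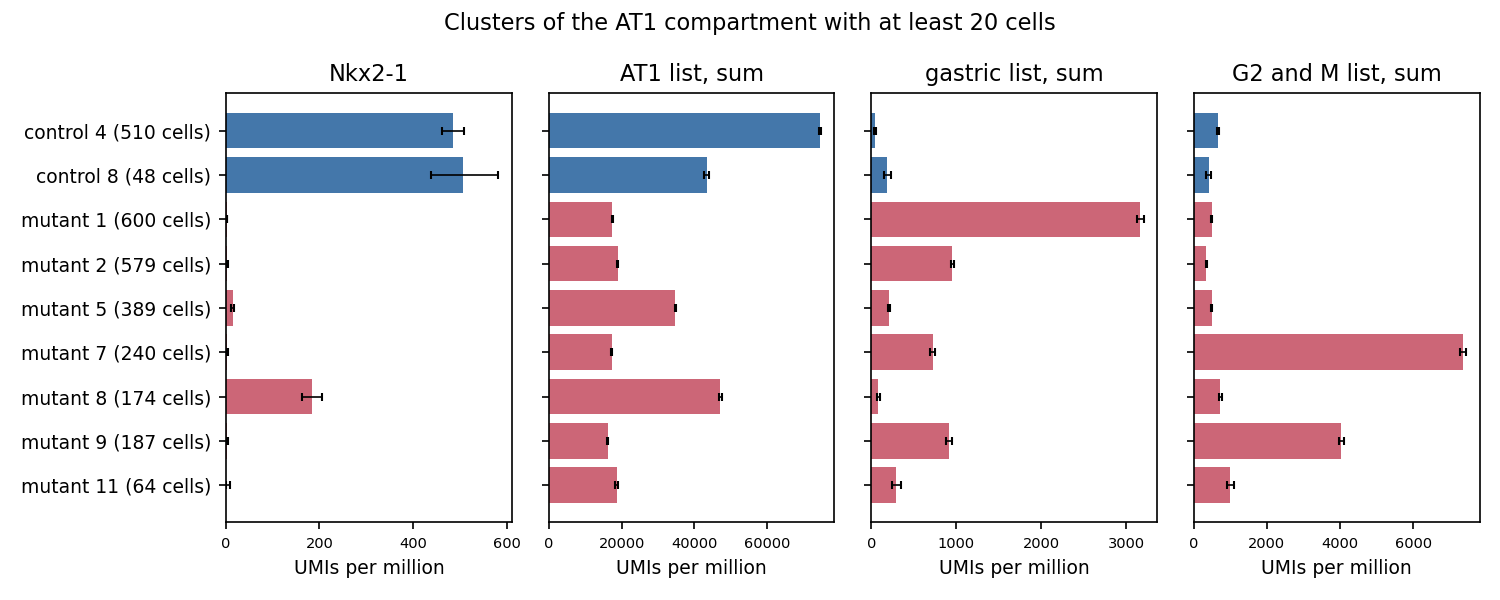
Clusters of the AT1 compartment with at least 20 cells, by library and cluster number, with bars for CPM of Nkx2-1 and of the summed AT1, gastric, and G2 and M phase lists and exact 95% Poisson intervals. Control cluster 4 had 74350 CPM of the AT1 list, and the gastric list was highest in mutant cluster 1, at 3169 CPM.

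In AT2-like cells, which were named by their AT2 markers, immediate early genes were lower and proliferation genes higher in the mutant. They numbered 1263 in the control and 212 in the mutant, with median depths of 7285 and 7219.5 UMIs. The control cells lay mostly in clusters 0 and 3 and 185 of the mutant cells in cluster 6, so values also compare those clusters. All genes had a median of 0.18 here and list medians are relative to it. AT2 genes had a median of -0.14 (-0.37 to 0.01, percentile 20.6), with 17 of 31 higher and a sign that depended on the scaling, since it was 0.03 before centring. Sftpc was 1.25-fold lower, Sftpb 1.20-fold lower and the desaturase gene Scd1, of surfactant lipid synthesis, 2.09-fold higher. AT1 genes had a median of -0.19 (-0.35 to 0.16, percentile 0.58), whose sign before centring was reversed in 10 of the alternatives tried. Ager was 1.60-fold lower. Lung transcription factor genes had a median of -0.36 (-0.61 to -0.04, percentile 0.01), with Etv5 1.41-fold lower.

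All 20 immediate early genes were lower in mutant AT2-like cells, with a median of -1.77 (-2.02 to -1.43, percentile 0), including the AP-1 subunit genes Fos (926 and 250.5 CPM, 3.70-fold) and Jun (857 and 219 CPM, 3.92-fold). These genes respond within minutes to handling and to growth factors. Of 35 G2 and M phase genes 34 were higher, with a median of 1.85 (1.42 to 2.12, percentile 100), and of 32 S phase genes 31 were higher, with a median of 0.77 (0.32 to 1.06, percentile 100). With free RNA subtracted these medians before centring were 4.35 and 3.72, against 2.03 and 0.94, and the immediate early median -3.02, against -1.59. With each library clustered alone the G2 and M phase median was 4.78. The kinesin gene Cenpe was 12.3-fold and the ribonucleotide reductase gene Rrm2 5.81-fold higher. Of 24 damage-associated genes 21 were higher, with a median of 0.60 (0.25 to 1.11, percentile 100), including Lgals3, a galectin gene (4.36-fold). Of 21 interferon and antigen presentation genes 18 were lower, with a median of -0.92 (-1.67 to -0.43, percentile 0), including Cd74 (1.60-fold lower). The largest ratios were those of Lrg1, a secreted glycoprotein gene (48.5 and 393 CPM, 8.10-fold), Dmkn (6.41-fold), Lgals3, the endocytic receptor gene Lrp2 (3.96-fold), Clip4 (3.42-fold), Hist1h2bc (3.42-fold), the cyclin gene Ccnd1 (3.26-fold), Nudt4 (3.18-fold), S100a6 (3.14-fold) and the metallothionein gene Mt2 (3.12-fold). The smallest were mostly immediate early genes: Cyr61 (5.08-fold lower), Jun, Fos, Chia1 (3.65-fold), Dusp1 (3.62-fold), Junb (3.59-fold), Klf6 (3.35-fold), Fosb (3.31-fold), Ier2 (3.23-fold) and Atf3 (3.17-fold).

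Endothelial cells, which line vessels next to AT1 cells and respond to their Vegfa, had close shares of Car4-high capillary cells in both libraries, although these came partly from different clusters. Car4-high capillary cells, the type next to AT1 cells, took 14.6% (11.8 to 17.7) of 591 control and 14.8% (11.8 to 18.3) of 487 mutant cells, and Plvap-high capillary cells 69.9% and 70.6%. Of the Car4-high cells, 82 of 86 in the control lay in cluster 4, while 33 of 72 in the mutant lay there and 39 in cluster 7. Arterial cells took 10.7% and 6.37% and venous cells 4.91% and 8.21%. Other resolutions altered these shares, with Plvap-high cells at 64.3% and 44.4% and arterial cells at 16.2% and 5.54% at resolution 2, and arterial cells at 5.58% and 6.16% at resolution 0.5. Plvap-high cells came mostly from clusters 1 and 2 in the control and cluster 0 in the mutant. Car4-high genes had a median of -0.01 (-0.35 to 0.10, percentile 53.7), which was 0.026 with doublets kept, and Plvap-high genes 0.13 (-0.16 to 0.37, percentile 95.7). The 18 measured VEGF response genes were split 9 and 9, with a median of 0.01 (-0.30 to 0.42, percentile 49.6) whose sign depended on the scaling. Among them the tip cell gene Esm1 was 6.02-fold lower and the vessel-remodelling gene Angpt2 3.12-fold lower, while Cd34 had 727 and 782 CPM. Plvap was 1.70-fold lower.

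Proliferation genes were also higher in the mutant endothelium, with 38 of 39 G2 and M phase genes higher (median 1.01, 0.68 to 1.13, percentile 100) and 28 of 34 S phase genes higher (median 0.33, 0.07 to 0.41, percentile 98.4). Mki67 had 35.3 CPM in the control and 206 CPM in the mutant (5.84-fold) and Top2a was 2.35-fold higher. Of 19 immediate early genes 17 were lower, with a median of -0.69 (-1.28 to -0.35, percentile 0), including the heat shock gene Hspa1a (5.17-fold lower). Besides Mki67, the largest ratios included Gm42418, an RNA gene that overlaps ribosomal RNA (9.97-fold), the neurotrophin receptor gene Ntrk2 (36.4 and 261 CPM, 7.18-fold), the matricellular gene Sparcl1 (5.22-fold), the hypoxia-induced Ankrd37 (4.86-fold), Amd1 (3.80-fold), Cdk19 (3.43-fold), Scaf11 (3.25-fold) and Secisbp2l (3.08-fold). The smallest were those of Ccl21a, a lymphatic chemokine gene (823 UMIs in 5 control cells), the surfactant genes Sftpb (12.7-fold lower) and Sftpc, Hspa1a, Zfp36 (2.44-fold), Wif1 (2.41-fold), Car2 (2.27-fold), Cyp4b1 (2.26-fold), Rps12-ps3 (2.14-fold) and Ctsh (2.11-fold).

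Mesenchymal cells, the fibroblasts and mural cells of the lung, had higher levels of alveolar fibroblast genes in the mutant library. Of 17 measured alveolar fibroblast genes 15 were higher in the mutant, with a median of 0.86 (0.18 to 1.12, percentile 100). Values over the whole lineage include its makeup, so a larger share of alveolar fibroblast-like cells enters this median. Some of the listed genes were also markers that named those cells. Macf1, a cytoskeletal linker gene, had 339 CPM in the control and 1075 CPM in the mutant (3.18-fold), and the growth factor gene Fgf10 was 3.03-fold and Limch1 2.35-fold higher. Alveolar fibroblast-like cells took 12.4% (10.5 to 14.5) of 1085 control and 21.5% (19.0 to 24.1) of 1016 mutant cells. They shared a cluster, but lay mostly in different clusters with all barcodes (11 control and 210 mutant cells, 137 and 7) and at resolution 2 (39 and 204, 94 and 13). With at least 1000 genes and under 5% mitochondrial counts they took 7.36% and 18.8%. Myofibroblast-like cells took 30.7% and 23.6%, but lay in different clusters, with 331 of 333 control cells in cluster 1 and 238 of 240 mutant cells in cluster 3. Their mutant share was above that of the control in other settings, at 38.3% against 30.7% with doublets kept, 38.0% against 31.4% at resolution 0.5, 37.5% against 33.8% with the stricter filter and 49.7% against 28.1% with each library clustered alone. Pericyte-like cells took 16.5% and 11.4%, also mostly in different clusters, with 134 control and 2 mutant cells in cluster 6 and 4 and 86 in cluster 8. Smooth muscle-like cells took 6.08% and 10.3% (13.2% and 10.0% at resolution 2), adventitial fibroblast-like cells 4.42% and 3.84%, and clusters without a name 29.95% and 29.3%.

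Myofibroblast and elastic matrix genes had a median of 0.01 (-0.32 to 0.24, percentile 82.1), with a sign that depended on the scaling. The elastin gene Eln was 1.21-fold lower and Tgfbi, a matrix protein gene, had 2247 CPM in the control and 743 CPM in the mutant. Collagen and fibrosis genes had a median of 0.14 (-0.03 to 0.34, percentile 99.3) but a sum of 16409 CPM in the control and 16064 CPM in the mutant, with Col3a1 at a ratio of 0.968 that lay above 1 (0.06 in log2) among cells with at least 1000 genes and under 5% mitochondrial counts. G2 and M phase genes had a median of 0.01 (-0.26 to 0.52, percentile 28.3), also with a sign that depended on the scaling, and -4.17 with free RNA subtracted. Of 20 immediate early genes 17 were lower, with a median of -0.74 (-0.85 to -0.43, percentile 0). The largest ratios included Gm42418, the detoxifying monooxygenase gene Fmo2, Pde10a (3.35-fold), Cpm (3.35-fold), Macf1, the Wnt inhibitor gene Wif1 (3.02-fold), Nrtn (2.72-fold), Nsd1 (2.72-fold) and the growth factor gene Igf1 (346 and 900 CPM, 2.60-fold). The smallest included Sftpc (6.31-fold lower, but 7.97 in log2 with free RNA subtracted), Hspa1a (5.01-fold), Qpct (2.84-fold), App (2.68-fold), Actc1 (2.67-fold), Pltp (2.56-fold), Gpc4 (2.46-fold) and Adk (2.29-fold).

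Immune cells of the mutant library held less RNA of inflammatory cytokine genes and lower shares of B and T cells. B cells took 42.5% (37.1 to 48.1) of 327 control and 17.9% (12.5 to 24.5) of 173 mutant cells, T cells 25.7% and 12.1%, alveolar macrophages 11.9% and 26.0%, monocytes 13.1% and 20.2%, interstitial macrophages 5.20% and 11.6%, and dendritic cells 1.53% and 12.1%. With each library clustered alone, the control held a neutrophil-like cluster of 50 cells and no monocyte or dendritic cluster, and the mutant held 19.9% dendritic cells and no neutrophil or interstitial macrophage cluster. At resolution 0.5 neither library had a dendritic cluster, and interstitial macrophages took 23.7% of mutant cells. Gene values over the whole lineage include this makeup. Another scaling moved the median of all genes by 0.13, so medians here are relative to it. Of 13 inflammatory cytokine genes 12 were lower, with a median of -1.30 (-2.85 to -1.08, percentile 0), which before centring was -1.21, but -1.91 with the stricter filter and -1.99 as a mean over cells. The cytokine gene Tnf had 106 CPM in the control and 6.28 CPM in the mutant (16.8-fold lower), the chemokine gene Cxcl2 was 3.99-fold lower and Il1b 2.21-fold lower. Of 15 repair macrophage genes 10 were higher, with a median of 0.62 (-1.14 to 1.12, percentile 100), including Lgals3 (1.66-fold), while Arg1 was 23.6-fold lower.

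Interferon and antigen presentation genes had a median of -0.50 (-0.75 to 0.19, percentile 0) in immune cells, with Cd74 1.37-fold lower. G2 and M phase genes had a median of 0.11 (-0.14 to 0.73, percentile 75.7), which before centring was 0.20, but -0.85 with free RNA subtracted and -0.040 with doublets kept. Of 20 immediate early genes 19 were lower, with a median of -1.53 (-1.78 to -1.16, percentile 0), including Junb (3.54-fold). This median was -1.45 before centring, but -2.54 with free RNA subtracted. The largest ratios were led by Clu (2.71 and 127 CPM, 47.0-fold), which had 8469 CPM in the mutant compartment, the fatty acid binding protein gene Fabp4 (7.30-fold), Mt2 (5.70-fold), Wfdc21 (5.48-fold), the Notch effector gene Rbpj (5.10-fold), Cd63 (4.75-fold), Ccdc88a (3.80-fold), the neutrophil-associated S100a8 (3.55-fold) and Cxx1a (3.50-fold). With each library clustered alone the S100a8 log2 ratio was -2.44. The smallest were those of Tnf, the phosphatase gene Dusp2 (9.97-fold lower), the B cell gene Vpreb3 (6.04-fold), Hspa1a (4.81-fold), Cxcl2, Jun (3.94-fold), Vps37b (3.92-fold), Gm12840 (3.89-fold), the nuclear receptor gene Nr4a1 (3.81-fold) and Junb.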

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

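All settings here were planned except the compartment without cluster 11 and the AT1-like clusters alone, which were tests chosen after the result was seen. Log2 values are before centring. With 1 library per group, a value counted as moved when it left its exact 95% interval. For genes and shares this is a counting interval, and for list medians the interval of a median over the listed genes. The latter can be wide, so a list median that stayed may still differ much in size. A value counted as reversed when its sign changed although its ratio interval excluded 0 or its percentile lay outside the central 95% of random lists. Over the main results, 190 values under alternatives gave 156 that stayed, 33 that moved and 1 that reversed. Over 38 described list medians, 570 values gave 520, 31 and 19, over 245 named genes 3057 values gave 2438, 602 and 17, and over 32 shares 224 values gave 192, 32 and 0. The 78 list medians not described gave 1021 values, of which 979 stayed, 27 moved and 15 reversed, in 12 lists. The compartment's gastric list ranged from 1.31 to 6.72 over its alternatives, the endothelial VEGF response list from -0.08 to 0.03, the immune cytokine list from -1.99 to -1.14 and the Car4-high shares from 14.6% to 15.1% in the control and 14.3% to 15.2% in the mutant, all within their intervals. The gastric interval was 1.31 to 7.14, so staying within it does not show a steady size. In AT1-like clusters alone the gastric list had too few measured genes for a median. No paired analysis was possible because each group has 1 library. Some named genes have no value with free RNA subtracted, since both libraries were then at the floor. In AT1-like clusters alone and in non-cycling cells, 19 values over 18 genes were not given, because both libraries had at most 3 UMIs or a library at 0 left the direction undetermined.

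The compartment's share of epithelial cells was 26.0% in the control with all barcodes, 35.1% with at least 1000 genes and under 5% mitochondrial counts, 52.3% with each library clustered alone and 15.9% with single cells classed one by one, and 91.1% and 83.0% in the mutant with the stricter filter and single cells. Clustered alone, 3 control clusters with 442 cells scored highest for AT2 markers but stayed unnamed, so they entered the compartment. In the classing of single cells, 460 control and 171 mutant cells lay between 2.5 and 10 marker UMIs per 1000, around the limit of 5.

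Nkx2-1 in the compartment was lower in each setting, at -5.31 scaled by the median ratio, -4.53 as a mean over cells, -3.58 over all epithelial cells, -5.96 with single cells classed, -3.68 in non-cycling cells and -1.38 in AT1-like clusters alone. Its share of cells with a UMI in the control was 45.3% with each library clustered alone, 42.2% over all epithelial cells, 89.1% not thinned and 36.7% thinned to 1000 UMIs. In the mutant it was 5.60% over all epithelial cells, 1.34% with single cells, 5.09% in non-cycling cells, 7.47% not thinned, 1.65% thinned to 1000 UMIs and 23.7% in AT1-like clusters alone. In AT2-like cells Nkx2-1 was -0.32 scaled by the median ratio and -0.39 by a trimmed mean, and the AT2 list there -0.22 by a trimmed mean.

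With each library clustered alone the AT1 list was -1.67 and the G2 and M phase list 2.56 in the compartment, Sftpd -0.57 there and S100a8 -2.44 in immune cells. Over all epithelial cells, which brings AT2 and airway cells in by construction, the AT1 list was -1.003, the G2 and M phase list 3.19, the YAP and TAZ list 0.48, the basement membrane list 0.25, the inflammatory cytokine list -0.24, the airway list -2.53, Sftpd -0.74, Il33 -0.28, Tspan8 0.32 and Atf3 -0.59. In AT1-like clusters alone, which leave out most mutant cells, the AT1 list was -0.65, the G2 and M phase list 1.57, the AT2 list 1.65, the intestinal list -0.23, the lung transcription factor list -0.18, the airway list -0.85, Sftpc 1.16, Cd74 0.97 and Atf3 -0.83. Non-cycling cells, 194 control and 275 mutant, were chosen for few cell cycle UMIs, and there the G2 and M phase list was -0.71 and Nasp -0.21. The limit was not scaled to depth, so it favours shallow cells, and cells above it were not thereby shown to cycle.

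With free RNA subtracted, the G2 and M phase list in the compartment was 3.61, the AT2 list 0.36 and Itgb1 -0.90. In mesenchymal cells Sftpc was 7.97, Cenpe -3.87 and Clu -4.15, and in immune cells Tubb4b was 1.36. The subtracted level was the lowest among the other lineages and not one measured in empty droplets. Such values can therefore reflect a library left at the floor. Itgb1 was -0.029 scaled by the median ratio. The stricter cell filter gave 1.13 for the alveolar fibroblast list and 0.058 for Col3a1 in mesenchymal cells.

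The AT1 list in AT2-like cells was near 0 and above it in most settings, at 0.022 with all barcodes, 0.17 with the stricter filter, 0.026 with doublets kept, 0.027 at resolution 0.5, 0.036 without listed genes, 0.29 with each library alone, 0.054 as a mean over cells, 0.14 with free RNA subtracted and 0.081 with listed genes of at least 1 or at least 100 UMIs. Where not given by construction, the cause was not tested.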

Other observations

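All tests of explanations given here were chosen after the result was seen. In the AT1 compartment of the mutant library, 10 of 11 measured inflammatory cytokine genes were higher, with a median log2 ratio relative to all genes of 2.04 (-0.11 to 7.63, percentile 99.97), which before centring was -0.24 over all epithelial cells and 0.050 over genes with at least 1 UMI, against 2.20 in the main analysis, 1.49 with each library clustered alone and 3.93 over genes with at least 100 UMIs. As for the gastric list, the limit on measured genes favoured genes seen in the deeper mutant class. Il18, an interleukin processed by inflammasomes, had 0 CPM in the control and 173 CPM in the mutant (at least 221-fold higher). Of 16 airway genes 11 were higher, with a median of 1.60 (-2.39 to 2.62, percentile 99.99), which had the opposite sign before centring over all epithelial cells (-2.53) and in AT1-like clusters alone (-0.85). Summed, the airway genes had 2583 CPM in the control and 569 CPM in the mutant. The keratin gene Krt4 was at least 38.5-fold higher there, while Sec14l3 was 22.4-fold lower. Of 16 measured myofibroblast and elastic matrix genes 13 were lower in the compartment, with a median of -1.59 (-2.11 to -0.83, percentile 0), which before centring was -1.43, but -0.65 with doublets kept and -2.12 in non-cycling cells. The elastic fibre gene Fbln5 had 1382 CPM in the control and 63.0 CPM in the mutant (21.9-fold lower), and the crosslinking enzyme gene Lox was 19.4-fold lower.

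Damage-associated epithelial genes were also higher outside the epithelium. In the mutant endothelium 15 of 20 were higher, with a median of 0.78 (0.09 to 1.34, percentile 100), and in mesenchymal cells 16 of 20, with a median of 0.80 (0.14 to 1.38, percentile 100). Krt19, an epithelial keratin gene, was 6.40-fold higher in endothelial and 7.53-fold higher in mesenchymal cells, at 31.3 and 25.8 CPM in the mutant against 2006 CPM in its AT1 compartment. Clu was 7.81-fold higher in mesenchymal cells, with the opposite sign (-4.15 in log2) once free RNA was subtracted. The libraries also separated outside the epithelium. In the main analysis, clusters with at least 95% of their cells in 1 library held 59.9% of control and 51.7% of mutant endothelial cells and 66.0% and 47.4% of mesenchymal cells. The control endothelial share was 38.1% without listed genes and 26.6% with the stricter cell filter. Immune cells had no such cluster in the main analysis, but at resolution 2 such clusters held 11.9% of control and 26.8% of mutant immune cells. With doublets kept, 1 such cluster held 15.4% of control and 1.20% of mutant immune cells.

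Gastric genes were higher in the mutant compartment. Free RNA or doublets with other cells were argued against, since the highest summed gastric level among the mutant's other lineages was 3.26% (at most 3.86%) of that in the compartment. A difference between the libraries alike in all cells was argued against too, since the ratio was 0.475 (0.395 to 0.568) in AT2-like cells, where Vsig2 gave most gastric UMIs, and 23.7 (20.8 to 27.1) in the compartment, although it was 5.46 (3.15 to 10.04) in mesenchymal, 1.86 (1.39 to 2.51) in endothelial and 1.36 (0.796 to 2.32) in immune cells. Within the mutant library, 85 compartment cells with at least 2 Nkx2-1 UMIs held 300.5 CPM of gastric genes, 82 cells with 1 UMI held 1351 CPM (1286 to 1420) and 2069 cells with none held 1475 CPM, so the first level was 20.4% (18.0 to 23.0) of the last. A link to Nkx2-1 loss in the same cells stays a hypothesis, since cells with 1 UMI lay close to those with none, and those with at least 2 may differ in origin and had a median depth of 9354 UMIs, below 12396 UMIs in cells with none.

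Immediate early genes were lower in the mutant library in each of the 5 classes, with a highest class median of -0.43 before centring, although that of the compartment was 0.48 with free RNA subtracted. Loss of Nkx2-1 in the cells that show it was argued against for AT2-like cells alone. They kept Nkx2-1 (ratio 0.908) and had a median of -1.59 (-1.84 to -1.25). The compartment median (-0.43, -0.82 to 0.06) lay 1.16 above, but cannot decide the question there. Its control and mutant cells lay mostly in different clusters, and it was -1.09 over all epithelial cells. AT2-like cells also lay mostly in different clusters, with 654 and 535 control cells in clusters 0 and 3 and 185 mutant cells in cluster 6. This limits the argument for AT2-like cells too. A difference in handling of the cells before capture and a response of the whole lung to the mutation both stay open, since with 1 library per genotype the class medians restate the pattern and decide neither.

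AT2-like cells took a lower share of the mutant epithelium. AT2 cells missed by the cluster names were looked for in the compartment. At least 5 AT2 marker UMIs per 1000 were seen in 5.77% (4.84 to 6.82) of mutant and 21.7% (18.4 to 25.3) of control compartment cells. At least 50 were seen in 1.65% and 4.09%. Few mutant compartment cells thus held AT2 markers, but clusters named by these markers had been left out, which lowers such shares by construction. AT2 cells that lost their markers would not be counted, so this explanation could not be decided. Dilution by more compartment cells as the whole cause was argued against, since there were 9.50 AT2-like cells per airway cell in the control and 3.07 in the mutant, a ratio of 0.324 (0.231 to 0.456) that was 0.513 (0.367 to 0.723) with each library clustered alone. Dilution in part stays open, since the airway share was also lower, at 6.79% and 2.74%, and the yield of each type was not tested. Deletion of Nkx2-1 in AT2 cells could not be decided, since the AT2-like cells that remained had a ratio of 0.908 (0.826 to 0.996), which cells that lost the gene and left the class would not alter, and a lower yield of AT2 cells from this mutant lung may apply too.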
